A study of Drosophila melanogaster with 4 samples.

How the data were processed

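Chromatin bound by the transcription factor Atonal was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in eye imaginal discs, the larval epithelia that form the compound eye, of third-instar Drosophila melanogaster. Per the labels' protocols, the animals carried a knock-in fusion of Atonal with green fluorescent protein and were kept at 25 degrees Celsius, and 800 discs from 400 larvae were fixed and sonicated. Of the sonicated material, 10% was kept as input and the rest was precipitated with antibodies against the fluorescent protein. The labels give 2 ChIP libraries and 2 input libraries, grouped by their titles. The labels do not say whether the numbered libraries came from separate collections of discs.

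The processed data used here are 1 peak list for the whole series, with no header, no sample names and no value for any single library. Bowtie2 2.2.1 is named in the submitters' processing notes. The peak caller, its settings, the genome build, and whether libraries were pooled before calling are not given in the sources used here. The list has 10 columns in the narrowPeak layout, and the meaning of each column was read from that layout and from the values. The deposited score equals 10 times the deposited −log10 q-value cut to a whole number in 100% of the peaks. The deposited fold ratio is the enrichment of ChIP over control. The deposited −log10 p-value and −log10 q-value are the significance the authors' peak caller gave each peak. The weakest listed peak has a q-value of 0.0499, just under 0.05. Starts were shifted to count from 1. Sequence names ending in Het are those of Release 5 of the fly genome. The gene table at hand describes Release 6, coordinates were not moved between builds, and no genome sequence was used here. Peaks are therefore named by position, and no gene, exon, transcript start or sequence motif is assigned to them.

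Each peak's fold and p-value together imply the levels they were computed from. Under the formula of MACS2, fold is (ChIP level + 1)/(control level + 1) and p is the upper tail of a Poisson distribution with the control level as its mean. A whole-number ChIP level that satisfies both was found for 6065 of 6065 peaks within 1e-04 on the −log10 p scale. The largest misfit was 8.29e-05, whereas the next-best whole number missed by at least 0.0247. The control level is the value each peak was compared with, which need not be a depth measured at that peak: 320 peaks share the lowest value, which is therefore read as a common floor. Values given as times the lowest are relative to that floor, and peaks at the lowest level are those with no control level above it. Neither level is a library total, and sequencing depth per library is unknown. In a check on simulated data, both levels were recovered in 100% of 6065 simulated peaks, while 0.214% of 6065 mismatched pairs passed the tolerance.

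The reference sequences were divided into 6 scaffolds of heterochromatin (Het), chromosome 4, the 2 Mb of each of the 5 large arms next to the centromere, and the rest of those arms (interiors). The centromere lies at the high coordinates of 2L, 3L and X and at the low coordinates of 2R and 3R. The position of the last peak on a sequence stood in for its length, so that lengths are lower bounds. Densities were compared by two-sided exact binomial tests with Clopper-Pearson 95% intervals, with Benjamini-Hochberg adjustment over 12 sequences or over the 5 large arms. Medians were compared by two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05, and 95% intervals from 2000 bootstrap draws, adjusted over 12 comparisons. Shares were compared by two-sided Fisher's exact tests, adjusted over 8 comparisons. Clustering was compared with 10000 random placements, two-sided. Intervals and p-values treat peaks as the units: they cover the spread over peaks in this list, not the spread between libraries, and neighbouring peaks are not independent. In simulated data a 4-fold difference in density was called in 100% of 100 draws and equal densities in 6%. A shifted median was called in 100% of 100 draws and an unshifted one in 8%. The simulated counts and values were independent of one another, so these rates do not cover lists with neighbouring peaks. The simulated sets also differed in size from the compared groups, and the check of medians drew fewer resamples than the 100000 used here.

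The test of each chromosome arm against its share of length, the stricter score threshold and the merging of peaks within 500 bp were fixed before the data were examined. The plan named assembled lengths, which the position of the last peak replaced because no genome was used. The ratio of the Het scaffolds to the large arms was not part of the plan. The rule for named items covered the genes nearest to the 20 peaks with the highest −log10 q, gene list members and the genes with the most peaks; it could be applied only as the 20 peaks themselves. The planned tests of transcript starts, genic features, Atonal E-boxes, other motifs, gene lists and cell type markers were not run, because they need a genome or annotation of the file's build. The division into compartments, the levels implied by fold and p, and the limits of 3-fold, 200 bp, 1.5 times the lowest control level and the lowest control level itself were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.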

Results

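Atonal, the proneural basic helix-loop-helix factor that starts photoreceptor formation by specifying R8, was mapped in the eye disc to learn where it binds the genome. Anti-GFP ChIP from discs carrying Atonal fused to green fluorescent protein was compared with input chromatin (2 ChIP and 2 input libraries). The deposited result is 1 list of 6065 peaks, which cover 977 kb on 12 reference sequences. Enrichment over control was low for most of them: the median fold was 1.87 (quartiles 1.70 and 2.12, lowest 1.41), and 87 peaks (1.43%) reached 3-fold. The largest fold was 6.28. Peaks were short, with a median width of 119 bp, quartiles of 85 and 177 bp, and a range from 69 to 4081 bp; 37.1% were under 100 bp. Because the list gives no value per library, none of these values has an error between replicates, and library depth is likewise unknown.

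Peaks were far denser on the heterochromatic scaffolds than on the chromosome arms. The 6 Het scaffolds, which hold repeat-rich sequence from around the centromeres and from the Y chromosome, carried 2790 peaks (46.0% of the list) at 301 peaks per Mb. The 5 large arms carried 3143 peaks at 26.5 per Mb, so that the scaffolds were 11.4 times as dense (95% interval 10.8 to 12.0, exact binomial test, p too small to be represented). Each of the 6 scaffolds had more peaks than its share of the summed length and each of the 5 large arms had fewer. The densest was 3LHet with 836 peaks at 327 per Mb, 6.98 times its expected number. 3RHet followed with 804 peaks (6.85 times), and 2RHet with 930 peaks (6.04 times). XHet had the smallest excess among the scaffolds, with 35 peaks and 3.66 times the expected number (exact binomial test, adjusted p = 1.85e-10). YHet held 91 peaks, 5.64 times the expected number (exact binomial test, adjusted p = 6.50e-38). Among the large arms, 3R had the lowest density, 18.5 peaks per Mb or 0.394 times the expected number (exact binomial test, adjusted p = 7.52e-164), and 3L the highest, 31.8 per Mb. The expected numbers spread the whole list, with its Het peaks, over the summed length, which lowers every large arm. In the interiors alone, 3R had 17.7 peaks per Mb and 3L 15.6, so their order came from the stretches beside the centromere. The implied control level was also raised at the Het peaks, with a median of 2.43 times the lowest level, a floor shared by 320 peaks, against 1.45 times in the arm interiors. A control level under 1.5 times the lowest was found at 15.1% of the Het peaks and 36.3% of the large arm peaks. Counting only these peaks, the ratio of densities was 4.74 (4.23 to 5.31, exact binomial), and counting only the 320 peaks at the lowest level it was 1.48 (0.999 to 2.13, exact binomial test, p = 0.0392). Such ratios divide the remaining peaks by the whole length of each sequence, because the length at a given control level is unknown, so they fall wherever the control level at the peaks is raised.

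**Figure D1:**
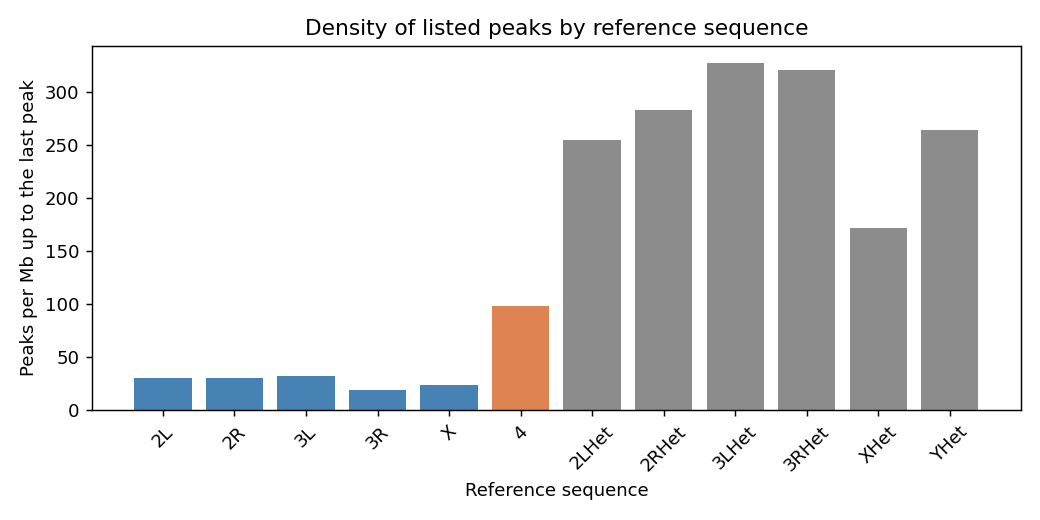
Bars give the number of listed peaks per Mb (vertical axis, starting at 0) on each reference sequence (horizontal axis), with the position of the last peak as its length; large arms are blue, chromosome 4 orange and Het scaffolds grey. The Het scaffolds lie between 172 and 327 peaks per Mb and the large arms between 18.5 and 31.8.

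Within the large arms, peaks gathered next to the centromere. The 2 Mb beside the centromere held 1271 peaks at 127 per Mb, against 1872 peaks at 17.2 per Mb in the interiors, a ratio of 7.38 (95% interval 6.87 to 7.93, exact binomial). The ratio was largest on 3L, at 13.8 (11.9 to 15.9). It was 9.68 (8.31 to 11.3) on 2L, 6.88 (5.85 to 8.09) on 2R and 5.71 (4.76 to 6.83) on X. On 3R it was 1.61 (1.20 to 2.13, exact binomial test, adjusted p = 0.00147), and its interval did not overlap those of the other arms. The fullest 1 Mb bins were 23 to 24 Mb on 3L with 246 peaks, 0 to 1 Mb on 2R with 199, 21 to 22 Mb on X with 182 and 22 to 23 Mb on 2L with 178, whereas the median bin of these arms held 15 to 17 peaks. The 2R bin from 2 to 3 Mb, counted with the interior, held 120 peaks, so the 2R ratio depends on the 2 Mb limit. Ratios per arm were not computed at other limits. On 2L, most of the 146 peaks in the bin from 21 to 22 Mb lay close together in a short stretch, nearly all at raised control levels. The intervals for 2L and for the pooled arms count these peaks as independent, and the ratios without that stretch were not computed. The control level was raised at the peaks beside the centromere too, with a median of 2.60 times the lowest level. A level under 1.5 times the lowest was found at 13.8% of them, against 51.5% in the interiors. Over whole lengths, the ratio was 1.98 (1.68 to 2.33, exact binomial test, p = 1.21e-14) for peaks under that limit and 0.602 (0.332 to 1.01, exact binomial test, p = 0.0547) for the 15 and 271 peaks at the lowest level.

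**Figure D2:**
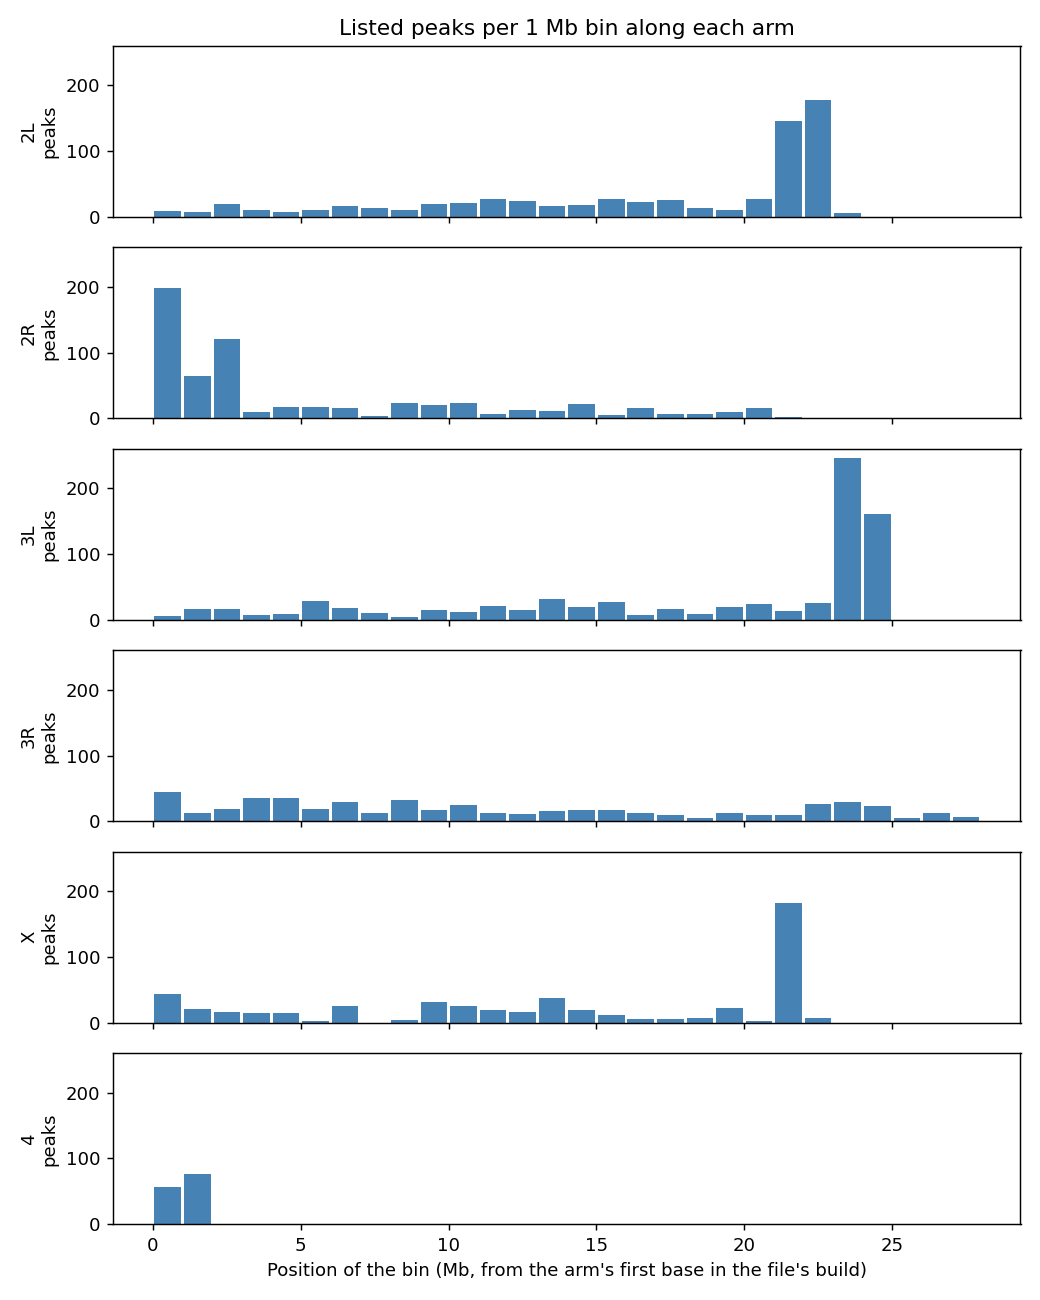
Each panel shows 1 arm; bars give the number of listed peaks (vertical axis) in each 1 Mb bin (horizontal axis, position in Mb). High bars stand at the right end of 2L, 3L and X and at the left end of 2R, and the highest bin, on 3L, holds 246 peaks.

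Chromosome 4, the small largely heterochromatic autosome, carried 132 peaks at 97.9 per Mb, 5.69 times the density of the arm interiors (4.73 to 6.79, exact binomial test, p = 3.71e-53). The ratio was 3.18 (2.40 to 4.14) after merging peaks within 500 bp and 9.24 (7.25 to 11.6) at or above the median score. Its peaks were wider, with a median of 156 bp against 113 bp in the interiors, and had a lower median fold of 1.73 against 1.93 (difference −0.20, 95% interval −0.24 to −0.17, permutation test, adjusted p = 1e-05). No chromosome 4 peak reached 3-fold (0 of 132, 95% interval 0% to 2.76%), an interval that includes the 2.72% of the interiors. The control level was raised, at a median of 3.57 times the lowest level, above the medians of the pooled Het scaffolds and of the large arms but below that of XHet (4.11 times). Only 7 of its peaks (5.30%) had a control level under 1.5 times the lowest, and 1 was at the lowest. Over whole lengths, the density ratio to the interiors was 0.585 (0.235 to 1.21, exact binomial test, p = 0.187) for the former and 0.298 (0.00751 to 1.67, exact binomial test, p = 0.273) for the latter, neither distinguishable from equal.

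Peaks also lay close to one another. In the arm interiors 42.0% of the peaks had another within 1000 bp, against 3.92% when the same number was placed at random (2.72% to 5.18% in 95% of placements, n = 1872 peaks, two-sided p = 2e-04, the smallest that 10000 placements can give). On the Het scaffolds the share was 71.5% against 50.4% by random placement, and beside the centromeres it was 72.0% against 30.3% (n = 2790 and n = 1271 peaks, p = 2e-04 for each by random placement). Random placement treats each peak as independent, so it cannot tell separate neighbours from 1 stretch listed as several peaks. These shares were not split by control level. Merging peaks within 500 bp left 4051 regions, 3059 of them with 1 peak. The regions with the most peaks, 16 each, were 2RHet 2086389 to 2094145 and 2L 22407877 to 22415807, the latter beside the centromere.

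The strongest peaks were distributed differently. A fold of at least 3 was reached by 51 of 1872 peaks in the arm interiors (2.72%) and by 23 of 2790 on the Het scaffolds (0.824%, odds ratio 3.37, Fisher's exact test, adjusted p = 1.07e-06). The odds ratio depended on the limits: it was 1.54 at a fold of at least 2.5, with 176 peaks in each compartment, and 5.45 among peaks at or above the median score. That score limit kept all 51 and 23 of the 3-fold peaks. It only lowered the totals, to 707 interior and 1635 Het peaks. At the highest ChIP level in the list, the control level was too high for a fold of 3 at 44.5% of the Het peaks and 27.5% of the interior peaks, and without these the odds ratio was 2.59 (Fisher's exact test, p = 1.28e-04). Among peaks under 1.5 times the lowest control level the shares were 4.46% and 4.03% and did not differ detectably (odds ratio 1.11, Fisher's exact test, adjusted p = 0.776). At the lowest control level the direction turned, with 9 of 271 interior and 4 of 33 Het peaks (odds ratio 0.249, Fisher's exact test, p = 0.0408). The median −log10 q went the other way, at 4.28 on the Het scaffolds and 3.01 in the interiors (difference 1.27, 95% interval 1.07 to 1.40, permutation test, adjusted p = 1e-05). Under the Poisson formula −log10 q rises with the levels at equal fold. Median ChIP and control levels were 81 and 42.6 on the scaffolds and 56 and 25.3 in the interiors. A higher −log10 q on the scaffolds is therefore not by itself a stronger enrichment. The difference was 0.395 (0.186 to 0.573) at or above the median score, a limit set on −log10 q itself, so this value does not test the difference. At the lowest control level the difference was not detectable (0.63, permutation test, p = 0.0848). Median fold was 1.87 on the scaffolds and 1.93 in the interiors, and median width was 120 and 113 bp. Both differences passed the permutation test (adjusted p = 1e-05 and 0.00669) but not with the centromere-proximal stretch set at 1 Mb (p = 0.108 and 0.159 by permutation). The fold needed to enter the list falls as the control level rises, so the lower Het median fold is not separate from the raised control level. Under 1.5 times the lowest control level the Het scaffolds had the higher median fold (difference 0.12, permutation test, p = 1e-05) and no detectable difference in width (−1.5 bp, permutation test, p = 0.567). Among peaks at or above the median score the difference in fold was −0.173 and the Het peaks were the narrower (−18 bp, permutation test, p = 0.00134).

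Of the 20 peaks with the highest −log10 q, 11 lay in arm interiors, 4 beside the centromere of 2L and 5 on Het scaffolds. The first was 3R 18309449 to 18309584, a 136 bp peak with a fold of 6.28 and a −log10 q of 49.8. The second, 3L 17352888 to 17354088, was 1201 bp wide with a fold of 5.54 and a −log10 q of 48.5. The third lay on 3RHet, 2136633 to 2136718, with a fold of 4.75 over 86 bp. Further interior peaks among the 20 were X 2685666 to 2687232 (4.54-fold, 1567 bp), 3L 13134640 to 13135138 (3.91-fold, 499 bp) and 3R 8334766 to 8334888 (3.77-fold, 123 bp). The X chromosome contributed 6 of the 20. Of these, X 9996974 to 9997061 (88 bp), X 6100919 to 6101004 (86 bp) and X 12331878 to 12331953 (76 bp) were under 100 bp wide and had control levels over 2 times the lowest. All 4 peaks beside the 2L centromere and all 5 on Het scaffolds were under 100 bp wide, against 4 of the 11 in the interiors.

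Strong peaks in the interiors tended to be wide. A fold of at least 3 was found in 32 of 339 interior peaks of at least 200 bp (9.44%) and in 19 of 1533 narrower ones (1.24%, Fisher's exact test, adjusted p = 2.30e-12). With a control level under 1.5 times the lowest, these shares were 31 of 94 (33.0%) and 12 of 871 (1.38%, Fisher's exact test, adjusted p = 7.31e-24). Fold and width are measures of the same called peak and so are not independent, and the limits were chosen after the values were seen. The 31 wide, strong, low-control interior peaks had a median width of 326 bp and a median fold of 3.30. They were spread over all 5 large arms, with 9 on 3L, 6 each on 2L and X, and 5 each on 2R and 3R. Examples, chosen after their values were seen, were 3R 10591232 to 10591558 (4.02-fold), 2L 19154936 to 19155277 (3.87-fold), 2L 6646262 to 6646651 (3.87-fold), 2R 20167676 to 20168238 (3.58-fold) and 2R 8655350 to 8655745 (3.45-fold). Of the 17 strong, low-control peaks on the Het scaffolds, 1 was at least 200 bp wide, against 31 of 43 in the interiors (Fisher's exact test, adjusted p = 6.45e-06). With a fold of at least 2.5 the odds ratio for width was 11.6 (52 and 5 wide peaks in the interiors and on the Het scaffolds) in place of 41.3. After merging peaks within 500 bp the regions were wide in 10 of 17 and 32 of 40 cases, and the difference was no longer detectable (Fisher's exact test, p = 0.113).

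**Figure D3:**
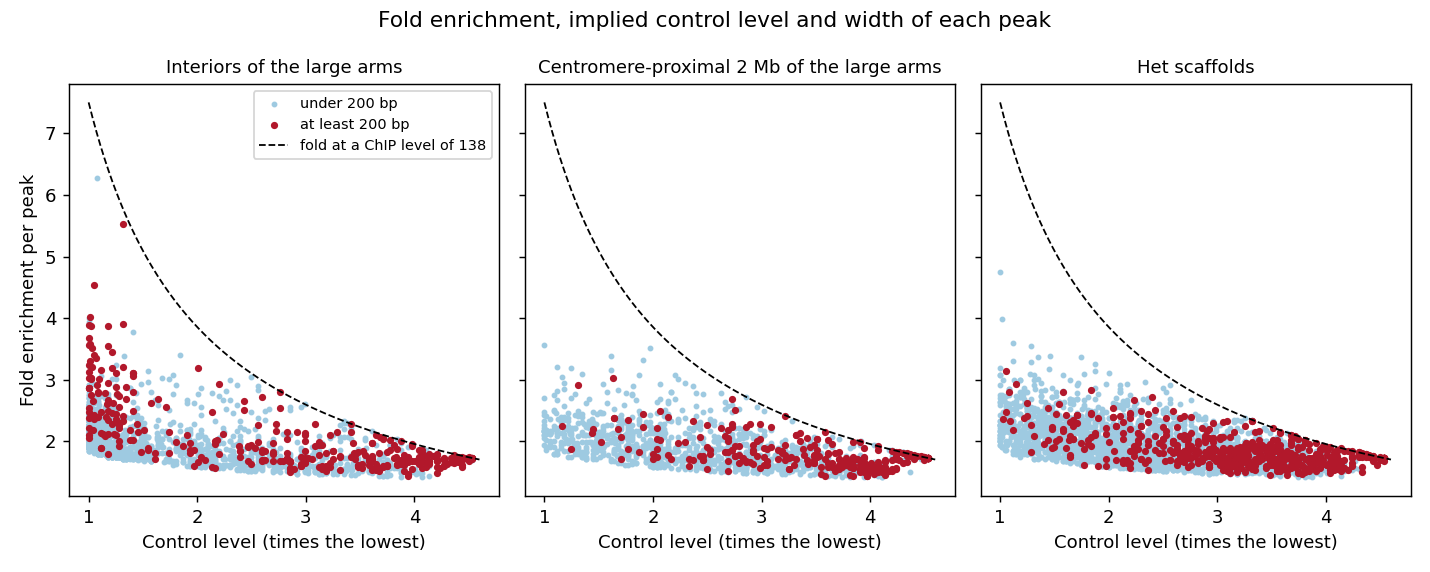
Each point is a listed peak of the arm interiors (left panel), the centromere-proximal stretches (middle) or the Het scaffolds (right), with its implied control level relative to the lowest (horizontal axis) and its fold enrichment (vertical axis); dark red points are at least 200 bp wide, light blue points narrower. The dashed line is the fold at the highest ChIP level in the list, 138, and 31 wide peaks of at least 3-fold stand in the left panel at control levels under 1.5.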

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

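Of 47 alternatives with a test, 33 kept direction and significance. Those chosen after seeing the data were all except the limit at the median score and the merging for the arms, and the merged peak number. For the arms these settings were applied to the Het to large arm ratio, which was itself not planned. The 33 are not all separate checks. The score limit left the comparison of wide, strong peaks unchanged at 41.3 and removed none of the 3-fold peaks. It also limits −log10 q itself, and merging keeps the peak with the highest −log10 q. The Het to large arm ratio at the lowest control level counted as kept (exact binomial test, p = 0.0392), although its interval reached 1. The list of 6065 peaks shrank to 4051 regions by merging, to 3066 at or above the median score, to 1570 with a control level under 1.5 times the lowest and to 320 at the lowest. Under the limit of 1.5, the density ratio of chromosome 4 to the interiors was 0.585 and not distinguishable from 1, the difference in median fold, Het minus interior, turned to 0.12, that in width was −1.5 bp and not detectable, and the odds ratio for 3-fold peaks fell to 1.11. At the lowest control level the odds ratio turned to 0.249. The density ratios there were 0.602 beside the centromere and 0.298 on chromosome 4, and the Het minus interior differences were 0.11 in fold, −8 bp in width and 0.63 in −log10 q; none of these 5 was past the threshold. The width difference turned to −18 bp at or above the median score. There the chromosome 4 ratio was 9.24, the odds ratio for 3-fold peaks 5.45, and the differences in fold and −log10 q −0.173 and 0.395. Merging gave 3.18 for chromosome 4 and 32.5 bp for width. A fold limit of 2.5 lowered the odds ratios for strong peaks to 1.54 and for wide, strong peaks to 11.6. With a centromere-proximal stretch of 1 Mb, the differences in fold (−0.018) and width (4 bp) lost significance, and merging lowered the odds ratio for wide, strong peaks from 41.3 to 2.80. That odds ratio had no finite value at the lowest control level, where 6 interior and 0 Het peaks were wide and strong. The Het to large arm ratio ranged from 1.48 at the lowest control level, with an interval that reached 1 (0.999 to 2.13), to 15.5 at or above the median score. The cause was not tested, except that the control limits remove peaks but no length, which lowers densities where control is raised, and merging lengthens regions by construction. No paired analysis was possible because the list has no value per library; leaving out a replicate, and other settings of the motif, gene and transcript start tests, were not run. Library depth is unknown, and no error between libraries can be given for the weakest peaks or for any others.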

Other observations

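The tests of the ceiling and of the Het concentration were chosen after the values were seen; that of split peaks was written before its result. A cluster on the X chromosome stood out among the 31 wide, strong, low-control interior peaks. Of these, 4 lay between 2684302 and 2690675, within 6374 bp, with widths of 236 to 1567 bp, folds of 3.02 to 4.54 and control levels of 1.00 to 1.05 times the lowest. It was the only place where any of the 31 lay within 10000 bp of another, and the other 27 stood alone. Which genes lie under these peaks is not analysed here.

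No peak had a ChIP level above 138, and 93 peaks shared that value, against 29 peaks at the level just below. A candidate explanation is that at most 1 read start per position and strand was kept and each read was extended by the smallest peak width of 69 bp, which allows a depth of no more than 138. The observed maximum equalled that depth exactly, but the explanation was written after both values were seen, so the match does not test it. The control levels above the lowest were whole multiples of 0.576, the highest control level divided by 138, within 0.01 of a step in 90.1% of 5745 peaks, against 2% by chance. If this holds, fold cannot exceed 7.50 anywhere in the list, and no peak with a control level above 2.59 times the lowest can reach 3-fold. Control levels above that limit were found at 78.0% of the peaks on chromosome 4, 50.1% beside the centromeres, 44.5% on the Het scaffolds and 27.5% in the interiors. The ceiling thus bears on the share of 3-fold peaks on chromosome 4 and on their lower share on the Het scaffolds. On chromosome 4 only 29 peaks lay within the limit, and 3.76% of such interior peaks reached 3-fold. Finding none on chromosome 4 is therefore not evidence of a lower share.

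Of the list, 46.0% lies on Het scaffolds. A candidate cause is sequence present in more copies in the genome than in the assembly, which raises the control as well. The excess over the interiors fell from 17.5-fold to 5.14-fold (4.57 to 5.76) under 1.5 times the lowest control level, where leaving out each scaffold in turn gave 4.54 to 5.56, and to 1.43-fold (0.965 to 2.06) at the lowest level. These ratios divide the remaining peaks by the whole length, so their fall only restates that the control level is raised at Het peaks, and neither speaks for nor against extra copies, which stay open. A test would need the length of sequence at each control level, which is not analysed here. Saturation of both libraries could give a fold of 1.73 from scaling alone, and 51 peaks, 22 of them on Het scaffolds, were at both maxima. Only 1.33% of the Het peaks (0.935% to 1.82%) were at the ChIP ceiling itself, too few for full saturation to account for the rest. That share does not count levels held down below the ceiling, so partial saturation stays open. Unequal recovery of heterochromatin in ChIP and input, antibody background and binding of Atonal itself stay open as well: the labels used here name no precipitation without the tagged protein, and no biological explanation was tested.

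Strong, low-control peaks were wide in the interiors (31 of 43) and narrow on the Het scaffolds (1 of 17 wide). Broad stretches on the scaffolds that were split into short peaks may account for this. After merging within 500 bp, 58.8% of the Het regions and 80% of the interior regions were wide, and the difference was no longer past the threshold (Fisher's exact test, p = 0.113). With 17 Het regions, and with neighbours that lie close together on these scaffolds in any case, splitting stays open and a real difference in shape is not excluded.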
